A study of Mus musculus with 2 samples.

How the data were processed

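The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) for histone H3 dimethylated at lysine 4 (H3K4me2), a mark found at active and poised promoters and at enhancers. The tissue was whole lung of mouse embryos of the B6NCrl strain at 15.5 days, male and female embryos pooled. There was 1 group of 2 biological replicates. Per the labels, replicate 1 was made from the lungs of 78 embryos and replicate 2 from those of 62 embryos, so the replicates are separate pools of animals. Replicate 1 joins 2 technical replicates and replicate 2 has 1. With 1 group there was no comparison between conditions. The comparisons the design allows are those between the replicates, and those between classes of genes or regions within the peaks.

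The authors deposited 4 peak lists on the mouse build mm10. Per the texts deposited with the samples, each replicate's list was made from its filtered alignments and 1 further input file, the pooled list from both replicates together, and the replicated list from the other 3 lists. The aligner, the peak caller, the filters and the rule by which a peak entered the replicated list are not given in the sources used here. Each deposited peak carries a signal value, a −log10 p-value, a −log10 q-value and a summit position from the authors' peak calling. What the authors' signal value is relative to is not given, so it was used only to rank, filter or describe peaks within 1 list. The lowest −log10 p in the deposited lists was 2.03 for replicate 1, 2.00 for replicate 2 and 2.01 for the pooled list, so peaks below a value of about 2 are not in the files. No read counts were used here and the sequencing depth of each replicate is unknown. A region with no peak is therefore one that did not pass the authors' threshold at that unknown depth and after those filters. The number of peaks per list can move with depth. How the filters treated reads that align to more than 1 place is unknown, so an absent peak at duplicated genes need not mean an absent mark.

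Coordinates are those of mm10, counted from 1. Genes were taken from the GENCODE M21 annotation of the same build (GRCm38) for chromosomes 1 to 19, X and Y, with 21853 protein-coding genes and 54361 transcription start sites (TSSs) of their protein-coding transcripts. The sequence gave chromosome lengths and the ratio of observed to expected CpG dinucleotides within 1000 bp of a TSS, the highest over a gene's TSSs. Peaks were assigned by priority to promoters (within 1000 bp of a TSS), exons, introns and the rest, called here outside protein-coding genes, which includes non-coding genes. A gene's promoter was counted as marked where a peak overlapped the 1000 bp on either side of any of its TSSs by at least 1 bp. A promoter domain was made by joining peaks over gaps of at most 1000 bp, and a gene's breadth is the length of the longest domain at its TSSs. Distal peaks lay over 2500 bp from every TSS and were given to the gene with the nearest TSS within 100000 bp. This nearest-gene rule names a neighbour and does not show which gene a region acts on. Unless another list is named, values come from the replicated list, with the same value from each replicate's own list beside it where it matters.

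The 31 gene lists, the tests, the alternatives other than those said to be added and the rule for named genes were fixed before the data were examined. All genes asked for were found in the annotation except Ahsp of the erythroid list. Marked and unmarked members of a list were compared with all other protein-coding genes by Fisher's exact test (two-sided, Benjamini-Hochberg adjustment over the 31 lists). Breadth was tested for the 25 lists with at least 5 marked members, by a two-sided permutation test of the median against 100000 random lists of as many marked genes. The number of distal peaks per gene was tested by a two-sided permutation test of the mean against 100000 random lists with as many genes from each of 10 classes of territory, the length of sequence from which a gene could receive peaks. The smallest p that these permutations can give is 2e-05. Overlaps and locations were set against 100 circular shifts of the peaks along each chromosome. Genes are not independent replicates, and neighbours such as the Hox genes share domains, so these p-values describe how lists differ within this tissue and not how embryos vary. Several genes are members of more than 1 list (Etv4, Etv5, Id2, Fgf9, Fgf10, Wnt2, Notch3 and Aldh1a2).

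The genes named are all those with a TSS in the 10 broadest promoter domains, the 10 with the most distal peaks (11 with ties), up to 4 marked members with the broadest domain and up to 3 unmarked members of each list, the genes nearest to the 3 promoter and the 3 distal peaks with the highest signal value, and all Hox genes. Other genes are named with a statement that they were chosen after their values were seen. The alternatives were each replicate's list alone, the pooled list, a −log10 q of at least 2, a signal value at or above the list's median, promoter windows of 500 and 2500 bp, the summit inside the window, merge gaps of 0 and 2500 bp, matching on CpG ratio (Cochran-Mantel-Haenszel test over 5 classes for marking, matched random lists for breadth, also over 5 classes), distal distances of 10000 bp, a reach of 50000 bp, no matching on territory, and stricter definitions of overlap. Merge gaps of 0 and 2500 bp for the difference between Hox groups were added after the data were seen. The p of the Cochran-Mantel-Haenszel test was taken from its exact conditional distribution. This form replaced the chi-square approximation after the values of the latter had been seen, because the lists are small, and no list changed its side of the threshold by it. For marking, these alternatives are given as differences in percentage points, and a list uncalled in both settings carries no direction. The list tests were tested on simulated values for the 21853 genes. With lists of 20 genes and no change, 3.43% (marking), 4 of each 100 (breadth) and 4.57% (distal peaks) of 175 lists passed an unadjusted 0.05, and all 10 changed lists were recovered in each test, at a 2-fold change for breadth and distal peaks. The simulated genes were independent, the simulated change in marking was large and recovery was counted without adjustment. It therefore does not give the power of the tests on the lists here. Peaks on unplaced contigs were left out of the gene comparisons, since gene positions were taken for the chromosomes alone. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.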

Results

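H3K4me2 was mapped by ChIP-seq in whole lung of 15.5-day mouse embryos, a stage at which the airway tree is still branching. The 2 biological replicates were pools of 78 and 62 embryos. The peak list of replicate 1 held 56428 peaks over 56.1 Mb and that of replicate 2 held 47443 peaks over 47.6 Mb. The pooled list held 56666 peaks and the replicated list 38775 peaks over 54.8 Mb, or 2.01% of the chromosomes. The median peak of the replicated list was 1015 bp wide, against 547 bp in replicate 1, 621 bp in replicate 2 and 597 bp in the pooled list. Read depth is unknown, so differences in peak number between the lists were not interpreted as differences between the pools.

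The first comparison asked how far the 2 pools of lungs gave the same regions. Of the replicate 2 peaks, 87.4% overlapped a replicate 1 peak (41445 of 47443, exact 95% binomial interval 87.1 to 87.7). Of the replicate 1 peaks, 67.4% overlapped a replicate 2 peak (38052 of 56428, interval 67.0 to 67.8). Circular shifts gave 4.02% and 3.38% on average, and at most 4.47% and 3.74%. The covered bases had a Jaccard index of 0.727, against 0.0105 for shifted peaks. Sharing rose with the signal value within each list. In replicate 1 it went from 22.9% in the lowest decile to 99.8% in decile 7 and 100% in deciles 8 to 10. In replicate 2 it went from 57.9% in the lowest decile to 99.9% in decile 6. The intervals cover counting error only, since neighbouring peaks are not independent.

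**Figure D1:**
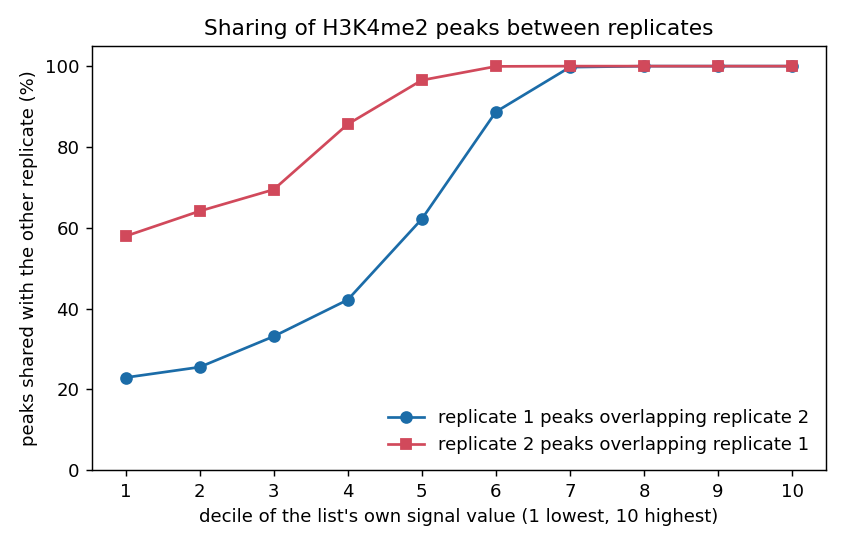
Share of each replicate's peaks (%, vertical axis) that overlap a peak of the other replicate, by decile of the list's own signal value (horizontal axis). Circles stand for replicate 1 and squares for replicate 2; they stand at 99.8% and 100% in decile 7 and at 22.9% and 57.9% in the lowest decile.

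At promoters the replicates differed little. Replicate 1 marked 15020 protein-coding genes and replicate 2 marked 14838, of which 14755 were marked in both, 265 in replicate 1 only and 83 in replicate 2 only. The promoter domains present in 1 replicate only were short, with medians of 293 bp in replicate 1 and 261 bp in replicate 2, against 2641 and 2401 bp for genes marked in both. Among the 265 were 13 list members, including Ehf (an epithelial factor), Hoxa11, the secretoglobin gene Scgb3a2, the retinol receptor Stra6, Rbp1, Dcx, Myf5, Ckm, Apoa1, Cd68, Ddx4, Pou5f1 and Olfr187. Among the 83 were 4, the type 2 cell gene Lamp3, the cardiac genes Nppb and Hand1, and the kidney podocyte gene Nphs1. Those of these genes outside the naming rule are listed because they complete the 2 sets, and so were chosen after their values were seen.

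The replicated list kept 38775 of the 56666 pooled peaks (68.4%), each with the same start and end. The kept share rose from 4.98% in the lowest decile of pooled signal values to 99.5% in decile 6 and 100% above it. Kept peaks had a median width of 1015 bp and peaks left out one of 248 bp. Of the replicated peaks, 92.1% overlapped a peak in both replicates' own lists.

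The mark was enriched at promoters. Promoter windows make up 2.37% of the chromosomes and held 47.9% of the bases covered by replicated peaks (46.2% in replicate 1, 51.4% in replicate 2), 18.5-fold the 2.59% of shifted peaks. Exons held 3.98% of the covered bases against 2.49% after shifting. Introns held 28.8% against 36.2%, and sequence outside protein-coding genes 19.4% against 58.7%. The share in promoters was 29.9% with windows of 500 bp. By number, 17131 peaks (44.2%) lay within 1000 bp of a TSS and 19693 (50.8%) over 2500 bp from every TSS. These were 33.7% and 58.1% (32800 distal peaks) in the replicate 1 list, and 41.1% and 50.6% in that of replicate 2. Promoter peaks were wider than distal ones, with medians of 1986 bp (quartiles 1282 and 2769) and 659 bp (444 and 993), and had higher signal values within the list, with medians of 25.7 and 5.04.

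The 3 promoter peaks with the highest signal value of the authors each covered a TSS, those of Stk32c (chromosome 7, 139187359 to 139189242, signal 71.9), which encodes a protein kinase, Ddah1 (chromosome 3, 145758106 to 145760047, signal 71.7), an enzyme that breaks down methylated arginines, and Cspg5 (chromosome 9, 110244590 to 110246730, signal 71.3), a proteoglycan gene. The 3 highest distal peaks lay in an intron of Macrod1 (chromosome 19, 7164063 to 7166734, signal 69.1), with Otub1 as the nearest TSS at 39.0 kb, over an exon, within both Prr7 and Dbn1 (chromosome 13, 55470917 to 55473604, signal 68.6), 6.65 kb from the nearest TSS, that of Prr7, and over an exon of Baiap2l2 (chromosome 15, 79260636 to 79262731, signal 67.5), 5.88 kb from the TSS of Slc16a8.

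Of the 21853 protein-coding genes, 14827 (67.8%) had a marked promoter, against 68.7% in the replicate 1 list and 67.9% in the replicate 2 list. Of the 31 gene lists 12 were marked more often than other genes, 8 less often, and 11 did not pass the test. Part of these calls ended against genes of like promoter CpG ratio, as given after the lists. Every member was marked among the lung epithelial transcription factors (22 of 22, adjusted p = 7.96e-04, Fisher's exact test against the 67.8% of other genes; 21 of 22 in the replicate 2 list), lung mesenchyme genes (20 of 20, adjusted p = 0.00126), endothelial markers (25 of 25, adjusted p = 3.16e-04), smooth muscle and pericyte markers (12 of 12, adjusted p = 0.0214) and alveolar type 1 markers (13 of 13, adjusted p = 0.0215). The same held for the signalling pathways of lung branching. By the same exact test, all 17 FGF genes (adjusted p = 0.00552), all 12 Hedgehog genes (0.0214), all 27 Wnt genes (1.30e-04), all 28 BMP and TGF-beta genes (8.95e-05) and all 18 Notch genes (0.00332) were marked. Ribosomal protein genes, most of which every cell uses, were marked in 77 of 80 cases (adjusted p = 2.44e-09, same exact test). The exceptions were Rpl10l, Rpl39l and Rpl3l, genes named as like a ribosomal protein, which the name pattern of the list takes in.

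Other lung lists were marked in part. Of the 12 alveolar type 2 genes 8 were marked, including the surfactant protein gene Sftpc, the surfactant lipid transporter gene Abca3, Lpcat1 and Muc1, while Sftpa1 and Sftpd, which encode the collectin surfactant proteins, and Lamp3 were not (66.7%, adjusted p = 1, exact test). Set against genes of like promoter CpG ratio, this list was marked 29.5 percentage points more often than its background (adjusted p = 0.00712, exact Cochran-Mantel-Haenszel test). Of the 20 airway genes 13 were marked (adjusted p = 0.933, exact test). The ciliated cell regulators Foxj1, Ccno and Trp73 and the factor gene Foxa3 were among them, and the club cell genes Scgb1a1, Scgb3a2 and Cyp2f2 were not. Of the cartilage genes 10 of 11 were marked, with Matn1 the exception (adjusted p = 0.160, exact test), and of the mesothelial genes 8 of 11, with Msln, Upk3b and Gpm6a the exceptions (adjusted p = 1). The retinoic acid list had 16 of 18 marked, without Cyp26c1 and Stra6 (adjusted p = 0.110, exact test), but passed the threshold in the replicate 1 list (adjusted p = 0.0315), the pooled list (0.0316) and with windows of 2500 bp (0.0316).

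Genes of other lineages were marked less often. Of the hepatocyte genes 1 of 17 was marked, Apoh, and Alb, Afp and Ttr were not (adjusted p = 7.90e-07, Fisher's exact test as above). Immune cell genes were marked in 2 of 14 cases (adjusted p = 1.70e-04, exact), the transcription factor genes Runx1 and Ikzf1, and not at Ptprc, Csf1r or Adgre1. Germ cell and pluripotency genes were marked in 4 of 20 (adjusted p = 6.58e-05, exact), namely Tex14, Dazl, Dppa3 and Tdrd1, and not at Ddx4, Sycp1 or Sycp3. Erythroid genes were marked in 5 of 14 (adjusted p = 0.0278, exact), including Tal1, Epor, Klf1 and Gypa, but not at Gata1 or the alpha-globin genes Hba-a1 and Hba-a2. Gene families of restricted tissues were almost unmarked. Marked members numbered 6 of 1134 olfactory receptors (the broadest at Olfr56, Olfr94, Olfr314 and Olfr1342; unmarked for example Olfr1416, Olfr1415 and Olfr1414), 1 of 329 vomeronasal receptors (Vmn1r4, not Vmn1r1, Vmn2r1 or Vmn2r2; adjusted p = 4.08e-161, exact), 1 of 57 keratin-associated proteins (Krtap17-1, not Krtap28-10, Krtap28-13 or Krtap5-2; adjusted p = 6.60e-26) and 0 of 64 defensins (for example Defb18, Defb41 and Defb23; adjusted p = 2.46e-31). The p of the olfactory list was too small for the software to represent.

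Some other-organ lists did not differ detectably from the background. Marked promoters were found at 20 of 24 neural genes (adjusted p = 0.164, exact test), including Pax6, Dlx2, Neurog2 and Slc17a7 but not Neurod6, Dcx or Slc17a6. They were found at 11 of 16 heart muscle genes (adjusted p = 1, exact test; not Myh6, Tnnt2 or Nppa), 6 of 14 skeletal muscle genes (0.113; not Myf5, Myog or Acta1), 12 of 19 gut, pancreas and thyroid genes (0.783; not Ins1, Ins2 or Gcg) and 7 of 10 kidney genes (1; not Slc12a1, Umod or Slc34a1). With only peaks whose signal value reached the median, the skeletal muscle (adjusted p = 0.0177, exact test) and gut lists (0.0468) passed as less often marked, and the skeletal muscle list also did with windows of 500 bp (-31.5 percentage points, 0.0286).

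Against genes of the same promoter CpG class, the calls ended for the lung epithelial factors (6.13 percentage points above the background, adjusted p = 0.398, exact Cochran-Mantel-Haenszel test), alveolar type 1 (11.1 points, 0.0807), FGF (1.68, 1), Hedgehog (6.90, 0.636), Wnt (2.00, 1), BMP and TGF-beta (5.04, 0.398), Hox 1 to 5 (14.0, 0.134), ribosomal (-0.988, 0.616) and erythroid lists (-1.96, 1). The mesenchyme (13.3 points, 0.0131), smooth muscle (39.8, 0.00381), endothelial (26.1, 1.06e-04) and Notch lists (15.01, 0.00381) passed, as did the less often marked lists other than the erythroid one. Most of the less often marked lists stood much nearer their background than in the main setting. Olfactory genes stood at -13.2 points (-71.0 in the main setting), vomeronasal at -6.34 (-68.6) and defensin genes at -11.7 (-68.0). Keratin-associated genes stood at -18.25 (-66.3), immune at -25.7 (-53.6) and hepatocyte genes at -29.0 (-62.0). Germ cell genes stood at -52.2 (-47.9). With the summit inside the window the epithelial factor, Notch and ribosomal lists passed, and 9 of the calls ended. By exact test these stood at 27.9 percentage points for alveolar type 1 (adjusted p = 0.0978) and 27.3 for smooth muscle genes (0.130), near the 32.2 of the main setting. The others stood at 20.8 for Wnt (0.0668), 19.6 for endothelial (0.119), 18.9 for Hedgehog (0.345), 17.9 for FGF (0.237), 15.6 for mesenchyme (0.273), 10.6 for BMP and TGF-beta (0.449) and 2.24 for Hox 1 to 5 (1). With the signal filter the smooth muscle (3.23 points, adjusted p = 1, exact test), endothelial (4.57, 0.732) and Hox 1 to 5 calls (16.6, 0.381) ended, and so did the erythroid one, at a difference near that of the main setting (-27.7 against -32.2 points, 0.0745).

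**Figure D2:**
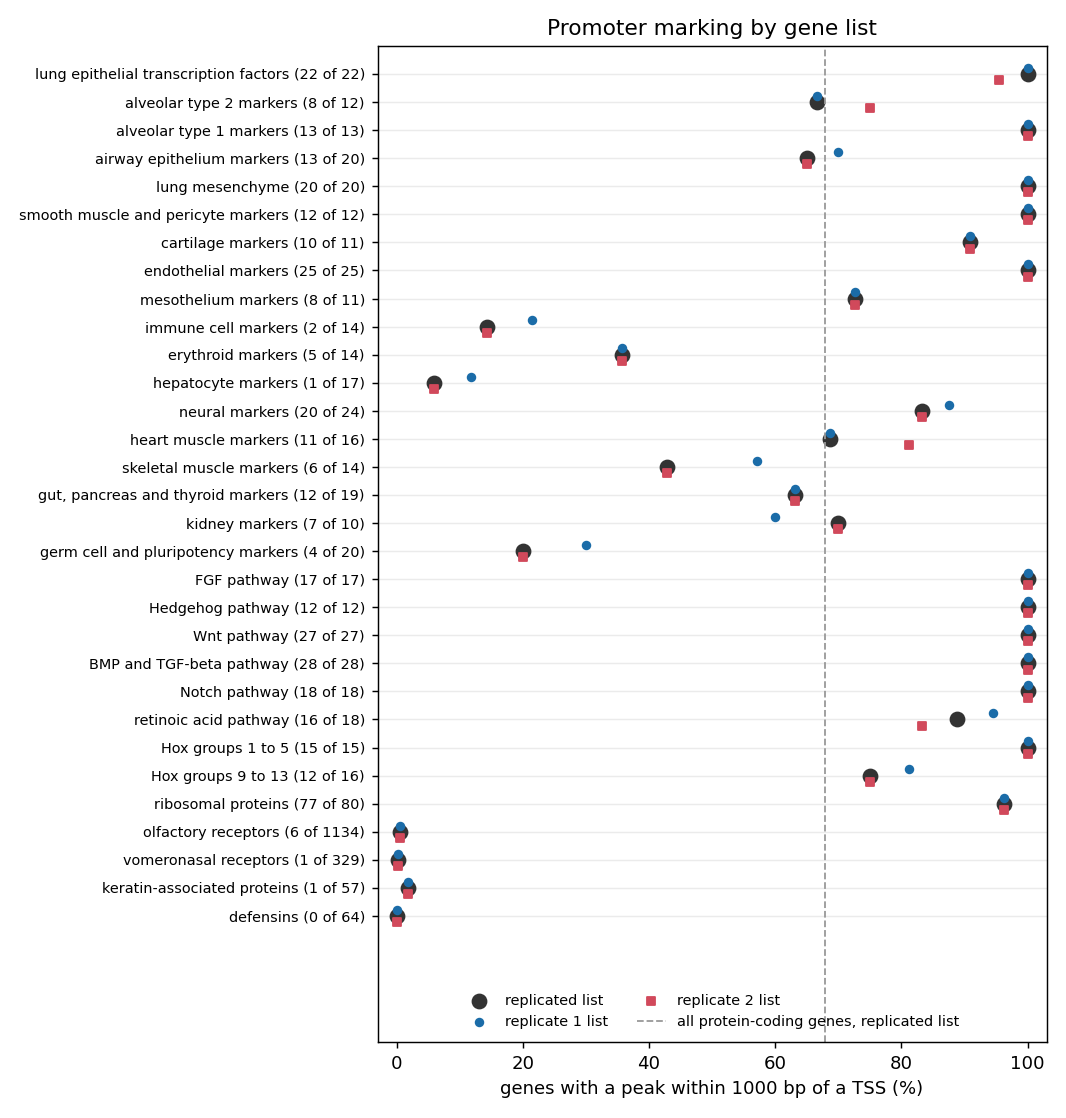
Share of genes with a peak within 1000 bp of a TSS (%, horizontal axis) for each of the 31 gene lists, with marked and total members in the replicated list in brackets. Large dots are the replicated list, small circles and squares the lists of replicates 1 and 2, and the dashed line is the 67.8% of all protein-coding genes; epithelial factor, mesenchyme, endothelial and pathway lists other than retinoic acid stand at 100%, and hepatocyte genes at 5.88%.

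Broad promoter domains were found at several regulators of lung development. All 14827 marked genes had a median breadth of 2596 bp (quartiles 1909 and 3517), and 73 domains were longer than 10000 bp. The broadest domain ran 56.8 kb over Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6 (chromosome 11, 96298689 to 96355480). Next came domains at Nr2f2 (chromosome 7, 70345668 to 70371873, 26.2 kb), which encodes the venous and mesenchymal nuclear receptor COUP-TFII, at Hoxa3 to Hoxa6 with the overlapping model Gm28308 (25.8 kb) and at Hoxa1 and Hoxa2 with 5730596B20Rik (24982 bp). The fifth was that of Nkx2-1 (chromosome 12, 56517403 to 56541263, 23.9 kb), the factor that specifies lung and thyroid endoderm. It measured 23.6 kb in replicate 1 and 21.4 kb in replicate 2. The list went on with Ptch1 (21.5 kb), the Hedgehog receptor gene, a domain across the neighbouring TSSs of Slc16a13, Bcl6b, 0610010K14Rik and Rnasek (21.2 kb), Nfib (21.0 kb), a factor gene needed for lung maturation, and the T-box genes Tbx5 (20.7 kb) and Tbx3 (20.3 kb).

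**Figure D3:**
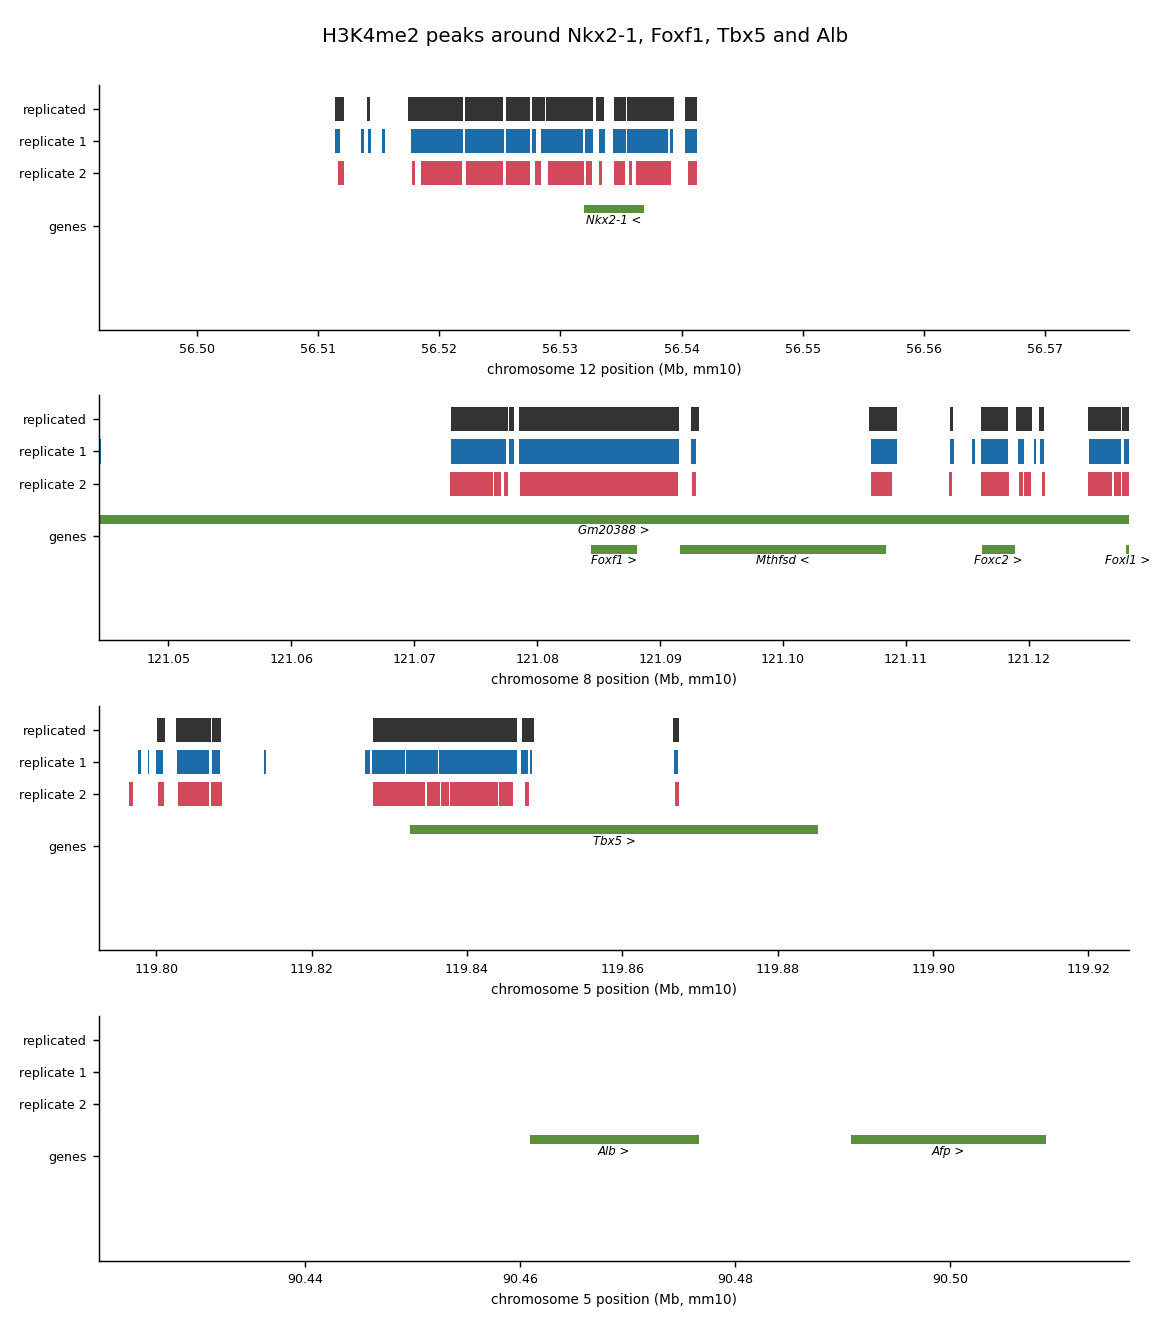
Peaks of the replicated list and of both replicates' lists (bars) around Nkx2-1, Foxf1, Tbx5 and Alb, with protein-coding genes beneath and position in Mb of mm10 on the horizontal axis; arrows give the strand. The Nkx2-1, Foxf1 and Tbx5 domains span 23.9, 20.2 and 20.7 kb, and the Alb and Afp region has no peak in any of the 3 lists.

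Of the 25 lists tested, 11 had broader and 5 had narrower domains than random marked genes. The lung epithelial factors had a median of 7626 bp, 2.93-fold that of random lists (2601 bp, adjusted p = 5e-05, from the smallest p that the permutations can give), led by Nkx2-1, Foxa1 (16.9 kb), Irx2 (15.5 kb) and Foxa2 (14.6 kb). The mesenchyme list had a median of 7192 bp (2.77-fold, same adjusted p), led by Tbx5, Tbx3, Foxf1 (20.2 kb), the mesenchymal Hedgehog target, and Tbx2 (17.8 kb). Endothelial genes had a median of 4469 bp (1.72-fold, same adjusted p), with Fli1 (8.64 kb), Prox1 (7.82 kb), Ets1 (7.80 kb) and Sox7 (7.51 kb) the broadest. The endothelial call ended when peaks were not joined over gaps (1.20-fold, adjusted p = 0.127, permutation test). In each replicate's own list the 3 medians were 7598 and 6830 bp, 6827 and 6731 bp, and 4645 and 3859 bp.

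The pathway lists were broader as well, each at the same adjusted p of 5e-05. Whether their domains also cover TSSs of neighbouring genes was not tested. FGF genes reached 5928 bp (2.28-fold), with Etv5 (12.6 kb), Fgfr2 (10.5 kb), the receptor of the branching signal, and the feedback inhibitors Spry2 (8.93 kb) and Dusp6 (8.87 kb). Hedgehog genes reached 5498 bp (2.11-fold), with Ptch1, Shh (10.8 kb), Gli2 (7.34 kb) and Boc (5.89 kb). Notch genes reached 5007 bp (1.93-fold), with Dll4 (14.4 kb), Hes1 (9.25 kb), Notch1 (8.68 kb) and Heyl (7.48 kb). Dll4 had 8.25 kb in the replicate 2 list and Heyl 4.78 kb in that of replicate 1. The retinoic acid list reached 4812 bp (1.85-fold), with Rxrb, Rara (9.43 kb), Rarg (8.17 kb) and Cyp26b1 (7.52 kb). The 9.98 kb domain at Rxrb was 3.61 and 3.95 kb in the replicates' own lists. Wnt genes reached 4723 bp (1.82-fold), with the target Axin2 (9.36 kb), Fzd7 (8.96 kb), Wnt5a (8.30 kb) and Wnt7b (7.28 kb). BMP and TGF-beta genes reached 4435 bp (1.71-fold), with Smad7 (14.7 kb), Id3 (10.1 kb), Id2 (9.30 kb) and Bmp5 (8.83 kb). Ribosomal protein genes exceeded random lists by less (3182 bp, 1.22-fold, adjusted p = 0.0022, permutation test), with the broadest at the neighbours Rpl13a and Rps11 (8.48 kb), at Rpl35 (7.27 kb) and at Rps18 (6.96 kb). That call ended without joining of gaps (1.04-fold, adjusted p = 0.647, permutation test) and with matching on CpG ratio (1.11-fold, 0.0514).

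Narrow domains were found in 3 of the other-organ lists. Gut, pancreas and thyroid genes had a median of 1200 bp (0.461 of random lists, adjusted p = 8.33e-05, permutation test), although Gata5 reached 6.58 kb, Lgr5 3.49 kb, Nkx6-1 3.04 kb and Slc5a5 1.88 kb (1.14 kb in replicate 2). Heart muscle genes had a median of 1279 bp (0.492, adjusted p = 9.64e-04, permutation test), with Myl3 (5.14 kb), Gata4 (4.81 kb), Ryr2 (2.49 kb) and Hand2 (2.27 kb) at the top. The list's median was 564 bp in the replicate 2 list (0.236 of random lists), and Gata4 had 2.01 and 2.18 kb in the replicates' own lists. Skeletal muscle genes had a median of 1560 bp (0.596, adjusted p = 0.0417, permutation test), with Mylpf (4.53 kb), Actn3 (2.12 kb), Pax7 (2.02 kb) and Pax3 (1.10 kb), and the median in the replicate 1 list was 993 bp (0.378 of random lists). The gut call ended with a merge gap of 2500 bp (0.904 of random lists, adjusted p = 0.586, permutation test), the heart call with a window of 500 bp (0.695, 0.0952) or the signal filter (0.884, 0.619), and the skeletal call with a window of 500 bp (0.776, 0.359) or without replicate 1, where the ratio moved little (0.655, 0.102). The 6 marked olfactory receptors had a median of 703 bp (adjusted p = 2.31e-04, permutation test).

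The other lists did not pass the test. Their medians were 3421 bp for alveolar type 1 genes (adjusted p = 0.107, permutation test), among them Ager (14.2 kb), Vegfa (7.66 kb), Cav1 (6.48 kb) and Pdpn (5.21 kb). They were 3262 bp for type 2 genes (0.266), with Muc1 at 9.55 kb, Sftpc at 6.69 kb, Lpcat1 at 3.87 kb and Abca3 at 3.66 kb, and 2822 bp for airway genes (0.618), with Ccno at 4.81 kb, Trp73 at 4.45 kb, Foxa3 at 3.99 kb and Foxj1 at 3.76 kb. They were 3021 bp for smooth muscle genes (0.362), with Notch3 at 5.54 kb, Smtn at 5.29 kb, Tagln at 4.75 kb (3.75 and 1.16 kb in replicates 1 and 2) and Myocd at 4.11 kb, and 3472 bp for cartilage genes (0.120), with Sox6, Runx2, Col2a1 and Hapln1 between 3.86 and 5.55 kb. Hapln1 had 2400 and 2155 bp in the replicates' own lists. The length given for Ager or another member is that of its whole domain, which can cover TSSs of neighbouring genes. For these lists that was not tested. The mesothelial (2559 bp, 0.918; Fgf9, Rspo1, Wt1 and Krt19), erythroid (2065 bp, 0.366), neural (2159 bp, 0.163) and kidney lists (1963 bp, 0.220; Eya1, Sall1, Six2 and Pax2) lay below the median of random lists. The kidney list turned its direction without replicate 2 (3314 bp, 1.26-fold), in the pooled list (1.04-fold) and with a merge gap of 2500 bp (1.48-fold), the erythroid list with that gap (1.31-fold), and the mesothelial list with a window of 500 bp (1.035-fold), none of them past the threshold. With matching on CpG ratio the type 1 (1.44-fold, adjusted p = 0.0251, permutation test), type 2 (1.65-fold, 0.0434), smooth muscle (1.65-fold, 0.0211) and cartilage lists (1.596-fold, 0.0211) passed as broader and the neural list as narrower (0.786, 0.0307). The type 1 list also passed in the replicate 1 list (1.57-fold, adjusted p = 0.0101, permutation test), in the pooled list (1.48-fold, 0.0233) and without joining of gaps (1.37-fold, 0.0459), the smooth muscle list in the pooled list (1.41-fold, 0.0482), and the neural list with the signal filter (0.686, 0.00692) and without joining (0.774, 0.0459). The smooth muscle list turned its direction in the replicate 2 list (0.840 of random lists) and with the signal filter (0.713), neither past the threshold, and when peaks were not joined over gaps, where it passed as narrower (0.654 of random lists, adjusted p = 0.0138, permutation test).

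**Figure D4:**
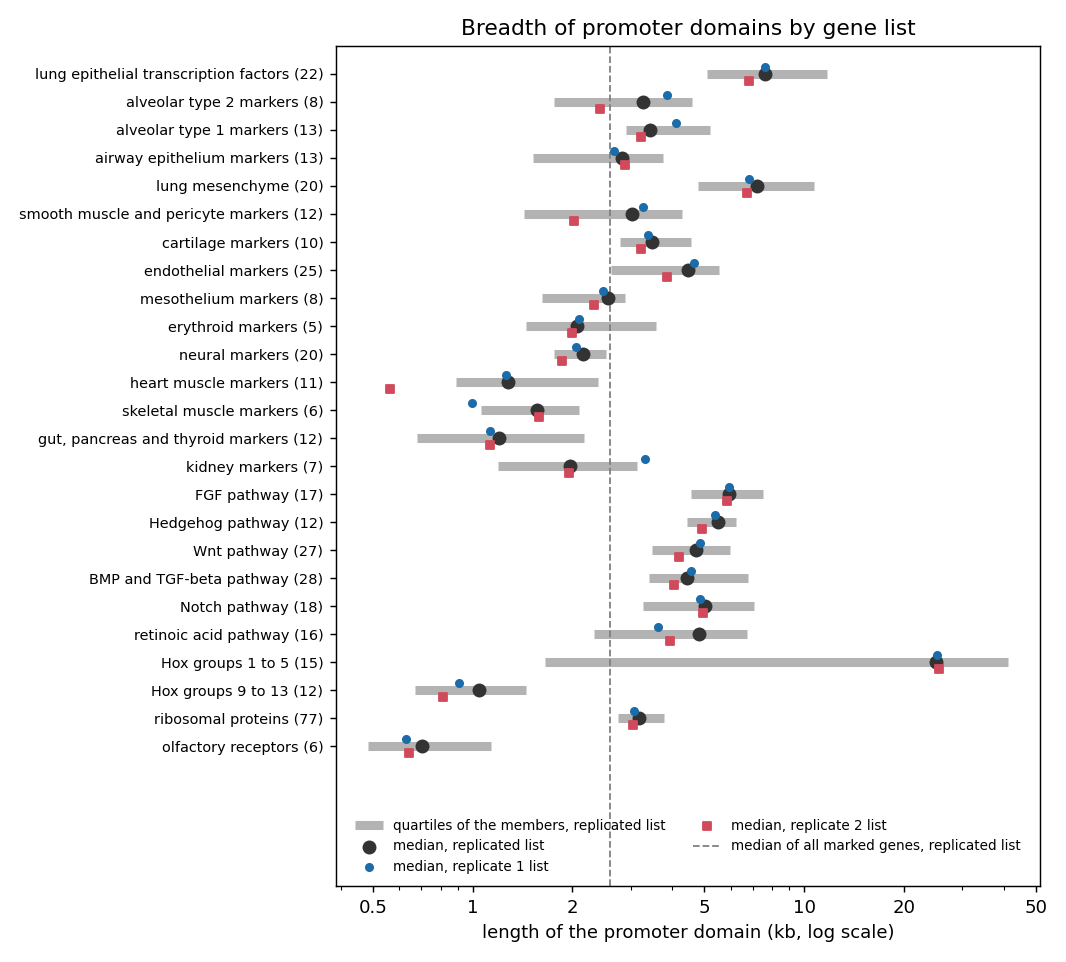
Length of the promoter domain (kb, log scale, horizontal axis) for the 25 lists with at least 5 marked members, whose number stands in brackets. Large dots are medians and grey bars quartiles in the replicated list, small circles and squares the medians in replicates 1 and 2, and the dashed line is the median of all marked genes at 2596 bp; Hox groups 1 to 5 lie highest at 24982 bp with peaks joined over 1000 bp, and below the lung epithelial factors (2.23-fold against 2.48-fold of random lists) without joining.

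Distal peaks were more numerous than expected at 9 lists and fewer at 3. The 16285 assigned distal peaks fell to 7287 genes, 0.745 per gene on average. Peaks over 2500 bp from every TSS that lie within a promoter domain were counted here too. One at Nkx2-1 is an example (chromosome 12, 56517403 to 56521935). The breadth and distal results are therefore not independent of each other. Genes of the FGF list had 4.94 each, 3.50-fold the number expected from their territory (adjusted p = 1.55e-04, permutation test, from the smallest p it can give), with 12 at Fgfr2. Notch genes had 4.17 (4.32-fold, same adjusted p), with 14 at Hes1. Lung epithelial factors had 4.09 (2.55-fold, adjusted p = 0.00131, permutation test), with 7 at Nkx2-1, some of them inside its promoter domain. Mesenchyme genes had 3.60 (2.49-fold, 0.00205), with 14 at Tbx3. Hedgehog (3.25, 2.47-fold, 0.0313), BMP and TGF-beta (3.11, 2.41-fold, 0.00131), Wnt (3.00, 2.19-fold, 0.00411), endothelial (2.92, 2.81-fold, 0.00131) and Hox 1 to 5 genes (1.33, 5.24-fold, 0.00131) passed too. The means per gene were higher in the replicates' own lists, which hold more distal peaks: in replicates 1 and 2 they were 7.53 and 5.88 for FGF, 5.89 and 5.17 for Notch, 6.77 and 5.32 for epithelial factor, 5.55 and 4.70 for mesenchyme, 6 and 4.75 for Hedgehog, 5.11 and 3.61 for BMP and TGF-beta, 5.22 and 3.74 for Wnt, 5.36 and 4.48 for endothelial and 1.80 and 1.73 for Hox 1 to 5 genes. Fewer than expected were found at olfactory receptors (0.0273 per gene against 0.285, adjusted p = 1.55e-04, permutation test), vomeronasal receptors (0.0517 against 0.713, same adjusted p) and defensins (0.0625 against 0.355, 7.44e-04).

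Single genes with the most distal peaks were Gse1 (28), Nfib (22), Zfp217 (19), Chd2, Irf2bpl and Smad7 (17 each), and Bach2, Bcor, Casz1, Mecom and Zfhx3 (16 each). These counts are not corrected for territory, which ran from 101 kb at Irf2bpl to 558 kb at Mecom. The replicates' own lists gave Gse1 48 and 37 and Nfib 43 and 25, and the other 9 genes between 20 and 32 in replicate 1 and between 18 and 29 in replicate 2. In the other 19 lists the permutation test was not passed. Adjusted p-values were 0.0795 for keratin-associated proteins, which did pass in each replicate's own list (0.0101 and 0.0106), in the pooled list (0.00775) and without matching on territory (6.20e-05), 0.143 for heart muscle, 0.168 for skeletal muscle, 0.197 for type 1 cells, which passed in the pooled list (2.34-fold, 0.0295), 0.261 for kidney and 0.268 for ribosomal genes. The remaining 13 lists lay between 0.383 and 0.984. Among the 12 calls, those for epithelial factors (1.88-fold, adjusted p = 0.298, permutation test), endothelial (1.70-fold, 0.410), FGF (2.62-fold, 0.131), Hedgehog (1.32-fold, 0.940), BMP and TGF-beta (2.57-fold, 0.0507), Hox 1 to 5 (3.84-fold, 0.201) and defensin genes (0.288 of the expected number, 0.210) ended when only peaks with a signal value at or above the median were used. That filter left out most distal peaks, since the median of the list was 10.5 and the upper quartile of all distal peaks 8.96. The kidney (6.16-fold, adjusted p = 0.00899, permutation test) and skeletal muscle lists (3.87-fold, 0.0491) passed with that filter. Those for mesenchyme (1.95-fold, 0.0751), Hedgehog (2.44-fold, 0.0648) and defensin genes (0.336, 0.173) ended when distal peaks had to lie over 10000 bp away, and that for Hox 1 to 5 without matching on territory (1.79-fold, 0.278). Without that matching the epithelial factor, mesenchyme, FGF, Hedgehog, Wnt and BMP lists stood between 4.03-fold and 6.63-fold, and olfactory receptors and defensins at 0.0367 and 0.0839 of the expected number.

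Hox clusters a and b were divided along their length. Hox genes give cells their position along the body axis, with low-numbered groups used towards the head. All 15 genes of groups 1 to 5 were marked and 12 of the 16 of groups 9 to 13, with Hoxa11, Hoxc11, Hoxc12 and Hoxd12 unmarked, a difference that did not pass the test (Fisher's exact test, two-sided, p = 0.101). With the summit inside the window the difference of 25 percentage points became -8.33 (p = 0.704, exact test), and with the signal filter 55 (p = 0.00385). The domains differed in length. Groups 1 to 5 had a mean breadth of 24194 ± 22961 bp (SD, n = 15 genes) and groups 9 to 13 one of 798 ± 680 bp (SD, n = 16 genes, unmarked as 0), which differed by permutation test (two-sided, p = 4e-05). The means were 19329 and 805 bp in replicate 1 and 17003 and 679 bp in replicate 2. The difference of 23396 bp was 11263 bp when peaks were not joined over gaps and 35403 bp with a merge gap of 2500 bp (permutation test, p = 4e-05 in both), alternatives chosen after the data were seen. The long domains lay in clusters a and b. In cluster b the 56.8 kb domain, which joins 5 peaks, ended within Hoxb6, on the side of Hoxb7. The replicates' own lists broke it up, with 48.4 kb as the longest part in replicate 1 and 31.9 kb in replicate 2, and with Hoxb2 at 7.35 and 23.8 kb. Hoxb7 and Hoxb8 shared a domain of 5.71 kb, and Hoxb9 (2.12 kb), Hoxb13 (0.748 kb) and Hoxb1 (1.63 kb) had short ones. In cluster a, Hoxa7 had 2.65 kb, Hoxa9 1596 bp (907 bp in replicate 1), Hoxa10 0.729 kb and Hoxa13 1.63 kb. In clusters c and d no domain of the replicated list exceeded 2.30 kb (Hoxc4, 3389 bp in replicate 1), whatever the group. Hoxc5 had 1.68 kb, Hoxc8 0.523 kb (195 bp in replicate 1), Hoxc9 0.497 kb (200 bp in replicate 2), Hoxc10 0.385 kb (221 bp in replicate 1) and Hoxc13 1.01 kb, and Hoxc6 was marked in replicate 2 only. Hoxd1 (1.45 kb), Hoxd3 (0.818 kb), Hoxd4 (0.490 kb), Hoxd8 (1.56 kb), Hoxd9 (1.40 kb), Hoxd10 (0.251 kb), Hoxd11 (1.31 kb, 574 bp in replicate 2) and Hoxd13 (1.09 kb) were alike in this. The genes of a cluster share domains, so the permutation p treats as separate what is partly the same measurement. As lists, groups 1 to 5 were broader than random marked genes (median 24982 bp, 9.62-fold, adjusted p = 5e-05, permutation test) and groups 9 to 13 narrower (1048 bp, adjusted p = 8.33e-05). The 9.62-fold of groups 1 to 5 was 2.23-fold without joining and 20.9-fold with a merge gap of 2500 bp, past the threshold in both. Marking passed for groups 1 to 5 (adjusted p = 0.00824, exact test) and not for groups 9 to 13 (0.933), whose difference from genes of like CpG ratio was -20 percentage points (adjusted p = 0.00286, exact Cochran-Mantel-Haenszel test).

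**Figure D5:**
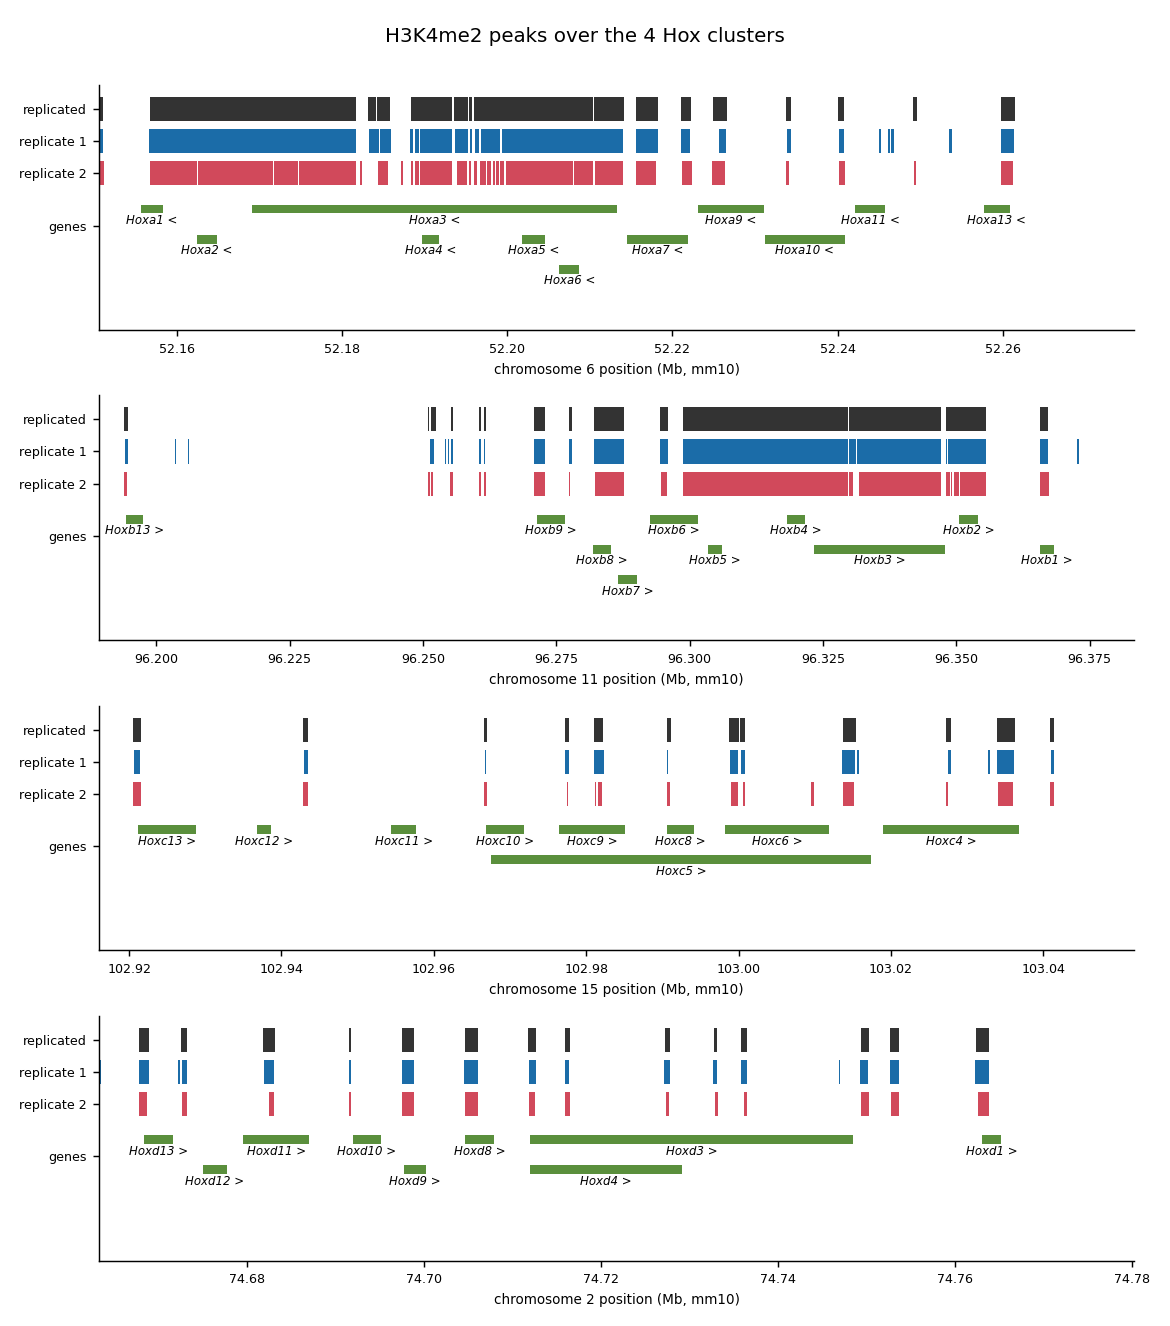
Peaks of the replicated list and of both replicates' lists (bars) over the 4 Hox clusters, with the Hox genes beneath, arrows for the strand and position in Mb of mm10 on the horizontal axis. Wide blocks lie over Hoxa1 to Hoxa6 and Hoxb2 to Hoxb6, while peaks over the higher-numbered genes and over clusters c and d are short, at most 5.71 kb at Hoxb7 and Hoxb8.

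Chromosome X carried fewer peaks. It had 5.44 peaks per Mb against 15.4 on the autosomes, a ratio of 0.354 (0.329 in replicate 1 and 0.345 in replicate 2). It also has fewer protein-coding genes, 5.54 per Mb against 8.41. Of its 948 protein-coding genes 497 were marked (52.4%), against 69.1% of autosomal genes. The Y chromosome had 7 replicated peaks, and the genes nearest to them were Uba1y, Kdm5d, Uty, Ddx3y and Gm21860, named after their values were seen. Both pools held male and female embryos in proportions that are not given in the sources used here.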

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

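The test that compares other-organ genes above and below the median promoter CpG ratio was chosen only after the result was seen. One result was picked out because it lies in data that no comparison above uses. The replicated list held 14 peaks on unplaced or unlocalized contigs of mm10, where protein-coding genes were not examined. Of these, 6 lay on 1 contig assigned to chromosome X, with 7 and 6 peaks there in the lists of replicates 1 and 2.

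Of 120 genes in the neural, heart muscle, skeletal muscle, gut, kidney, hepatocyte and germ cell lists, 61 had a marked promoter in this lung tissue. Cells of other organs carried along in dissection stay open. The genes below the median CpG ratio were marked in 23.2% of cases (16 of 69), less often than other genes below that median (37.4%, Fisher's exact test, two-sided, p = 0.0170), but the bound set for this test was wrong, because a small admixture need not lift genes of 7 organs to the rate of all other genes, and the lists differed (against genes of like CpG ratio 5.03 points for heart muscle, -29.0 for hepatocyte and -52.2 for germ cell genes). Above the median 88.2% were marked (45 of 51), more often than below it (Fisher's exact test, p = 4.07e-13) but below the 98.4% of all genes there, so that CpG content may account for part of the marking, and 73.8% of the marked genes lay above the median, between the bounds of 50% and 75% that had been set. No biological explanation was tested, since the series has 1 group.

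The broad domains of the lung epithelial factor, mesenchyme and endothelial lists, 67 genes with a median of 5564 bp against 2596 bp in random lists, could have had 3 technical sources. Joining of neighbouring protein-coding promoters was argued against. Each of the 67 genes was the only protein-coding gene with a TSS at its domain. Their median of 5564 bp still exceeded the 2438 bp of random genes alone in theirs (permutation test, p = 2e-05, the smallest it can give). Promoters of non-coding genes were not counted as neighbours, so joining with those stays open. CpG content was argued against as the whole source, with 2611 bp in matched random lists (same p), and so was the joining over gaps for the 3 lists together, with 4343 bp against 2269 bp when no gap was allowed (same p), though not for the endothelial list by itself, which fell from 1.72-fold to 1.20-fold of random lists (adjusted p = 0.127, permutation test) while the epithelial factors (2.48-fold) and mesenchyme (2.09-fold) passed. The signal per cell and the number of cells of each type could not be tested from peak lists, and no biological explanation was tested.

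Replicate 1 had more peaks than replicate 2. Of the replicate 1 peaks without a partner 96.5% lay in the lower 50% of that list's own signal values, and 99.95% of those of replicate 2 did so in theirs, so this share does not tell why replicate 1 has more. Depth, the joining of 2 technical replicates and the embryos themselves stay open, since depth is unknown.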

How the results depend on the processing

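The merge gaps for the difference between Hox groups and the exact form of the Cochran-Mantel-Haenszel test were chosen only after the results were seen. No paired analysis was possible because the series has 1 group. Depth and the filters on the alignments are unknown and limit what an absent peak shows. For the gene lists, 705 of 774 combinations of a list result and an alternative stayed on their side of the threshold, 40 calls were lost and 24 gained in the same direction. Of the 705, 45 without a call changed sign. With a call in either setting 5 changed sign: against genes of like CpG ratio, ribosomal (-0.988 points), type 2 (29.5) and Hox 9 to 13 marking (-20), Hox 9 to 13 marking with the signal filter (-38.5), and smooth muscle breadth without joining (0.654). A summary count of genes or lists held if it stayed within 1.5-fold of the main value. A fall from 12 lists to 9 held, for example. For the summary values 82 combinations held and 21 did not. Except where the construction of an alternative shows it, the cause was not tested.

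Stricter overlap changed the shared peaks, 67.4% of replicate 1 and 87.4% of replicate 2, to 60.4% and 83.1% (50% of the peak covered) and 54.7% and 65.1% (reciprocal 50%). A −log10 q of at least 2 gave 69.7% and 89.5% and kept 73.8% of pooled peaks, and equal numbers of the top peaks gave 92.4% and 97.2%. The share of covered bases in promoters (47.9%; 46.2% to 51.4% without either replicate) was 29.9% and 66.9% with windows of 500 and 2500 bp, which hold less and more sequence by construction, and 59.1% with peaks at or above the median signal. Lists marked more often fell from 12 to 3 with the summit inside the window (broad domains can have it elsewhere) and to 5 with CpG classes. Narrower lists numbered 3 with the window of 500 bp against 5, and 2 with the signal filter, where skeletal muscle, Hox 9 to 13 and olfactory genes had too few marked members to be tested and the neural list (0.686) was gained. The signal filter also left out most distal peaks. Lists with more distal peaks numbered 5 against 9 with it, of which kidney and skeletal muscle were gained. For Hox groups 1 to 5 minus 9 to 13 the difference in marking of 25 points was 55 with the signal filter (Fisher's exact test, p = 0.00385) and -8.33 with the summit rule (p = 0.704). The ratio of peaks per Mb of X to autosomes, 0.354, was 0.329 to 0.345 without either replicate and 0.311 in the pooled list. Marked genes ranged from 13863 to 15075, against 14827 in the main setting.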

Other observations

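The descriptions of long non-coding RNA genes and of transcription factor families were chosen only after the broadest domains had been seen. Long non-coding RNA genes had not been counted above. Of 10155 such genes of the annotation 3133 (30.9%) had a peak within 1000 bp of a TSS, and of the 8120 with a TSS over 2500 bp from every protein-coding TSS 1361 (16.8%) were marked there. The broadest domains clear of protein-coding promoters, named after their values were seen, lay at Carmn (chromosome 18, 61651002 to 61666504, 15.5 kb), a smooth muscle and cardiac transcript, at Gm26698 (10.1 kb), C230035I16Rik (9.92 kb), Neat1 with the antisense Frmd8os (9.65 kb) and Malat1 (9.09 kb). The imprinted H19 had 6.64 kb and Dnm3os, the host of a mesenchymal microRNA cluster, 6.28 kb. A domain of 5.70 kb at 1700021F13Rik lay upstream of Tbx5 on chromosome 5 (119802590 to 119808290).

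The marked members of 9 families of developmental transcription factors were described next. The 116 marked Fox, Tbx, Sox, Gata, Irx, Nkx, Meis, Nfi and Klf genes had a median of 3731 bp against 2935 bp in random lists matched on CpG ratio. No p is given, since 11 of these genes stand in the 20 broadest domains from which the families were picked, and whether such families hold broader domains as a class stays open. The families were uneven inside. Meis genes had a median of 15.9 kb (3 genes), Irx 9.49 kb (6 genes), Nfi 8.25 kb (4 genes), Gata 7.67 kb (5 genes) and Klf 4.615 kb (16 genes). The Nkx (2.03 kb, 13 marked of 14), Tbx (2.42 kb, 11 of 13), Sox (3.45 kb, 19 of 19) and Fox genes (3.50 kb, 39 of 44) had lower medians. Those lay within the quartiles of all marked genes (1909 and 3517 bp). In the Nkx family Nkx2-1 reached 23.9 kb and the next, Nkx6-2, 3.9 kb; in the Tbx family Tbx5, Tbx3, Tbx2 and Tbx4 had 20.7, 20.3, 17.8 and 11.5 kb. The zinc finger genes named Zfp, set beside them without a test, had a median of 2.20 kb (323 marked of 365).

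Genes with broad promoter domains also had more distal peaks. To see whether broad domains merely reach into the distal class, the marked genes above the 90th percentile, with a breadth of at least 4814 bp (1484 genes), were counted with peaks over 10000 bp from every TSS. They had 1.54 such peaks per gene against 0.779 in random marked genes of the same territory (permutation test with 10000 lists, two-sided, p = 2e-04, the smallest it can give). The count did not leave out peaks of a gene's own domain. In the 110 genes with a domain over 10000 bp such peaks can lie past the cut, as at Nkx2-1 (56517403 to 56521935). The 110 genes were not counted apart from the others, so whether reaching over explains the excess stays open. The relation is one across genes, which are not independent replicates.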
